A study of Mus musculus with 6 samples.

How the data were processed

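Gene expression was measured by poly(A) RNA sequencing of mouse E14Tg2a embryonic stem cells that had been differentiated as embryoid bodies for 5 days. Per the labels' protocols, the embryoid bodies were dissociated, dead cells were gated out with propidium iodide, and cells were sorted by the excitation ratio of a nuclear Grx1-roGFP2 sensor. The series' design text states that the 10% most oxidized and the 10% most reduced cells were taken from each of 3 populations, named A, B and C. Stranded mRNA libraries were sequenced as paired ends, per the labels' protocols. This gives 6 libraries, 3 oxidized and 3 reduced. Nothing in the labels says whether the 3 populations were clones, cultures or days, so p-values measure the spread between these populations.

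The authors deposited 1 table of 31265 genes, with an FPKM value (fragments per kilobase of transcript, scaled to the library's total) for each gene and library, per the file headers. The submitters' processing notes name cutadapt, FastQC, HISAT2, StringTie, edgeR and the mm10 genome build, without versions, and how fragments that match several places were counted is not given in the sources used here. The authors' deposited fold column equals the ratio of the mean FPKM of the 3 oxidized libraries to that of the 3 reduced libraries, with 1e-04 in place of a mean of 0. The authors' deposited log2 column is the log2 of that ratio. The authors' deposited p-value and q-value columns come from their own test of oxidized against reduced libraries, and the file headers do not name that test. Whether the counting used the strand is not given in the sources used here, so a gene and its antisense partner are not told apart.

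FPKM values are not counts, so no count test was run. Low FPKM values multiplied by transcript length fell on whole steps, within 2%, for 34.7% to 38.0% of values, and on whole or intermediate steps for 46.0% to 49.7%, so reads could not be recovered. The size of the step gives an estimated depth of 1.18e+07 to 1.79e+07 fragments per library, and the shallower libraries of population C carry more counting error in low genes.

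For the comparison, FPKM values plus a pseudocount of 1 were put on the log2 scale, and genes with a mean of at least 1 FPKM over the 6 libraries were kept, which left 12191 genes. limma 3.58.1 in R 4.3.3 fitted the group alone (lmFit, then eBayes with a mean-variance trend and without robust estimation). Genes with a Benjamini-Hochberg adjusted p under 0.05, two-sided, were called, with no minimum change. All adjusted p-values for genes come from limma. Log2 differences are oxidized minus reduced on the log2(FPKM + 1) scale, which understates the change of low genes. FPKM levels are means ± SD over 3 libraries.

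Each of 32 gene lists fixed before the data were examined was tested against all other tested genes with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 31 lists with at least 5 measured members. The lists cover pluripotency states, germ layers and the cell types that embryoid bodies or the live-cell gate could hold, redox and metabolic pathways, stress responses, the cell cycle, imprinted genes, Hox genes and histones. For each list the members called over all genes were counted, and those passing when adjusted over the list alone. Some lists share members: 6 of the 14 genes of the germ cell list and 3 of the 21 genes of the primitive and visceral endoderm list are also in another list.

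The genes named in the text were chosen by a rule set before the data were examined. The rule takes the 8 largest increases and the 8 largest decreases among called genes that have a proper symbol, a mean of at least 5 FPKM and groups that do not overlap. It adds the 3 members with the smallest p in each called list, the most abundant measured member of every other list, and Pou5f1, Nanog, Sox2, T, Sox17, Pax6, Gclm and Txn1. Genes named outside this rule were chosen after their values were seen, and the text says so.

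Oxidized and reduced cells came from the same 3 populations, per the series' design text, so the population letter pairs the libraries. Deviations from the group means correlated across genes within a letter at r = -0.06 for A, 0.07 for B and 0.20 for C, where the highest r with another letter was 0.13, 0.12 and -0.05. A fit with the population as a block was planned as an alternative. Its values are given for the results whose call or count it changes, for some genes only as a range. Other alternatives were median-ratio scaling, quantile normalization, limma without the trend, no filter, a mean of at least 5 FPKM, a pseudocount of 0.1, a change of at least 2-fold, leaving out each library, and camera with an estimated correlation. Leaving out the oxidized libraries A and B together, and leaving out genes that share sequence, were added after seeing the data.

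Genes were located and their overlaps and sequence read from the GENCODE vM21 annotation of GRCm38, the assembly called mm10. A gene counts as sharing sequence when at least 25% of its 50-base stretches also occur in transcripts of another annotated gene. Of the 97 called genes 14 do, and their values are uncertain, since fragments may have been split between copies. Of the named genes, H2ac13, Eno1b, Igf2, Dppa2, Zscan4f, Ftl1, mt-Co1, Ccnb1 and Krt8 share sequence in this way. Of the 69 named genes 8 overlap another gene in the table: Nnat, Col3a1, Myl3, Col4a2, Ina, Ftl1, Igf2 and Gclm. Gene ontology terms were taken from the deposited table and tested with a one-sided hypergeometric test against the 10619 tested genes that carry a term, over 2736 terms.

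The tests were checked on simulated libraries of the same 12191 genes for the oxidized against reduced comparison. limma recovered 45% of genes changed by 1 on the log2 scale and 86% of those changed by 2, against 12% and 79% with the block, and made 7 false calls. Camera called the 1 list that was raised and 0 of the others. The simulated genes varied independently and held no population effect. False list calls from correlated genes, and any gain from the block, were therefore not checked. In the real libraries the estimated correlations of the called lists ranged from 0.04 to 0.52. Figures and sequence searches used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.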

Results

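Mouse E14Tg2a embryonic stem cells carrying the Grx1-roGFP2 sensor in the nucleus, a fluorescent protein that reports the glutathione redox state, were differentiated as embryoid bodies, and gene expression was measured at day 5. Live cells of 3 populations (A, B and C) were sorted into the 10% most oxidized and the 10% most reduced, which gave 3 oxidized and 3 reduced libraries. The comparison asks whether cells that differ in nuclear redox state at day 5 differ in the genes of the lineages that form in embryoid bodies. The estimated depth was 1.58e+07, 1.52e+07 and 1.18e+07 fragments in the oxidized libraries A, B and C, and 1.79e+07, 1.70e+07 and 1.25e+07 in the reduced ones. Between 11911 and 12404 genes reached 1 FPKM in each library.

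Abundant ribosomal and mitochondrial transcripts set the oxidized libraries A and B apart from the other 4. A locus annotated as ribosomal RNA (CT010467, chr17:39846353-39848827) held 1410 and 1736 FPKM in them, against 34116 to 43825 FPKM in the others. The cytochrome oxidase transcript mt-Co3 held 2710 and 1525 FPKM against 112 to 199, and the cytokine gene Mif held 2496 and 2512 FPKM against 803 to 1297. The shift was smaller for the 13 mitochondrially encoded mRNAs together, which summed to 7348 and 5160 FPKM against 2324 to 3917. The first principal component carried 42.9% of the variance and placed oxidized C, at -0.45, between oxidized A and B, at -30.8 and -34.8, and the reduced libraries, at 15.2 to 28.5. Across genes, which are not independent replicates, oxidized C correlated more with reduced C (r = 0.969) than with oxidized A (r = 0.955) or B (r = 0.948). CT010467, mt-Co3, Mif, Eno1 and the Zscan4 genes were chosen for display after their values were seen.

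**Figure D1:**
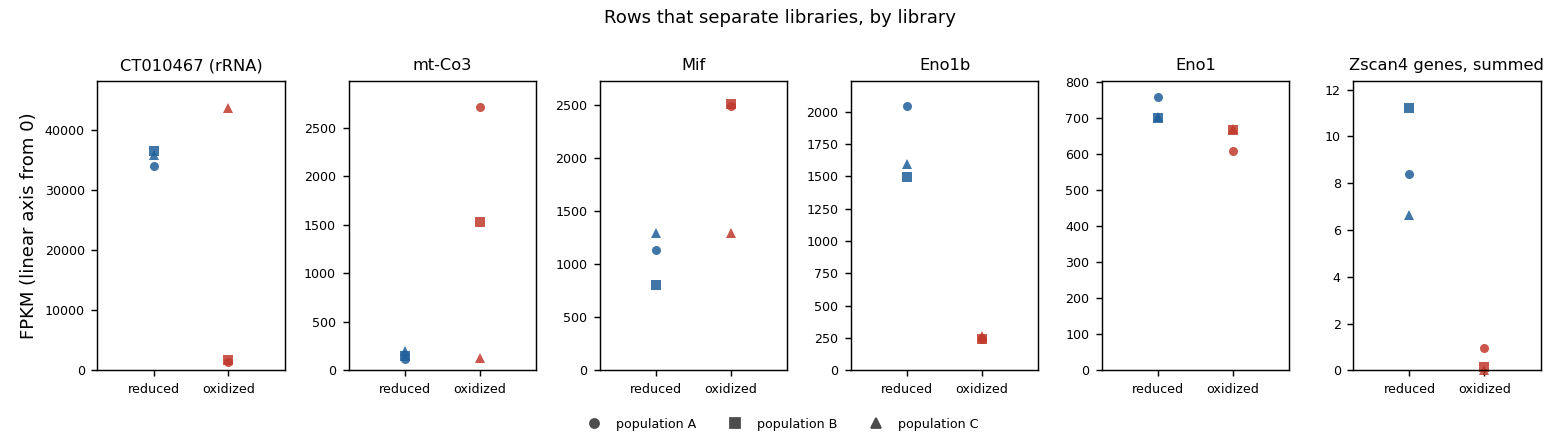
FPKM of a ribosomal RNA locus, mt-Co3, Mif, Eno1b, Eno1 and the sum of 9 Zscan4 genes in each library, on linear axes from 0, with 1 point per library and the marker giving the population. Oxidized A and B stand apart for CT010467, mt-Co3 and Mif, while all 3 oxidized libraries lie below all 3 reduced ones for Eno1b, Eno1 and Zscan4.

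Among called genes with a proper symbol and a mean of at least 5 FPKM, the 8 largest increases in oxidized cells were those of H2ac13, Spink1, Crabp1, Frzb, Cd248, Nnat, Col3a1 and Wfikkn1. Crabp1, which binds retinoic acid in the cytoplasm (chr9:54764748-54773110), was at 211 ± 53.4 FPKM in oxidized and 55.4 ± 9.06 FPKM in reduced cells (n = 3 each, log2 difference 1.89, SE 0.23, adjusted p = 0.0167). In the blocked fit the adjusted p of Crabp1 was 0.0613. Frzb, a secreted Wnt antagonist (chr2:80411970-80447625), was at 17.0 ± 1.499 against 4.13 ± 0.893 FPKM (log2 difference 1.82, SE 0.18, adjusted p = 0.0103). The collagen gene Col3a1, the stromal membrane glycoprotein gene Cd248 and the imprinted gene Nnat rose by 1.70, 1.76 and 1.71 on the log2 scale. Wfikkn1, a secreted protein with protease inhibitor domains, rose by 1.66 and the trypsin inhibitor gene Spink1 by 2.29. Spink1 was at 19.5 and 19.8 FPKM in oxidized A and B and 5.47 FPKM in oxidized C, and the log2 fold change of Spink1 was 1.17 without oxidized A and B (adjusted p = 0.114). Without the mean-variance trend its adjusted p was 0.0505. The histone gene H2ac13 (chr13:21716422-21716814) rose from 32.2 ± 11.8 to 213 ± 50.9 FPKM, a value that is uncertain because 90.1% of its sequence stretches occur in other histone genes. Col3a1 and Nnat overlap other genes in the table, so their values may include fragments of these.

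Among the same genes, the 8 largest decreases were those of Eno1b, Tdgf1, Pla2g1b, T, Dppa2, Ap1m2, Trh and Calcoco2. T (brachyury), a transcription factor of the primitive streak (chr17:8434423-8442496), was at 4.51 ± 1.06 FPKM in oxidized and 14.7 ± 0.232 FPKM in reduced cells (n = 3 each, log2 difference -1.53, SE 0.18, adjusted p = 0.0158). Tdgf1, a co-receptor for Nodal, fell from 129 ± 32.7 to 41.8 ± 7.63 FPKM (log2 difference -1.58, adjusted p = 0.0323). In the blocked fit T and Tdgf1 had adjusted p-values of 0.0601 and 0.0564. The pluripotency-associated gene Dppa2 fell by 1.44 on the log2 scale, with 29.1% of its stretches shared with other genes, and Trh, the precursor of thyrotropin-releasing hormone, fell by 1.29. The phospholipase gene Pla2g1b, the adaptor subunit gene Ap1m2 and the autophagy receptor gene Calcoco2 fell by 1.54, 1.37 and 1.24. The enolase gene Eno1b (chr18:48045335-48048412) had the largest decrease of these, from 1712 ± 289 to 249 ± 13.8 FPKM (log2 difference -2.76, SE 0.18, adjusted p = 0.00103). This value is uncertain, as 84.5% of its stretches occur in other enolase sequences.

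**Figure D2:**
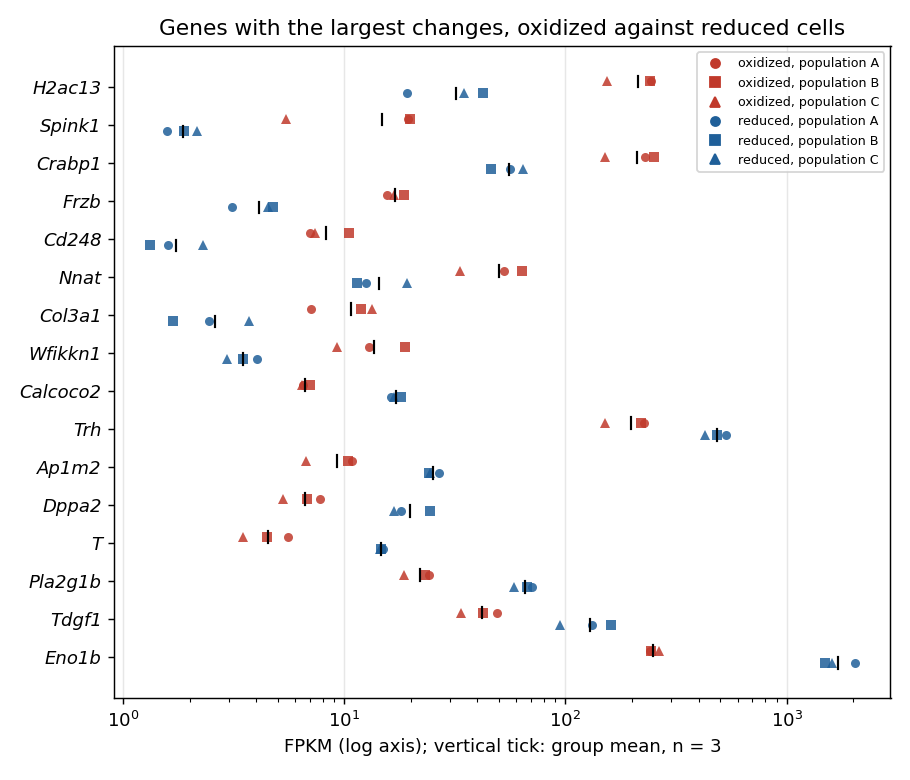
FPKM, on a log axis, of the 8 genes with the largest increase and the 8 with the largest decrease in oxidized cells under the naming rule, with 1 point per library, the marker giving the population and the vertical tick the mean of 3 libraries. The oxidized and reduced libraries do not overlap for any of the 16 genes, as the naming rule requires, and Eno1b lies between 240 and 265 FPKM in oxidized and between 1498 and 2041 FPKM in reduced libraries.

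Of 12191 genes tested with limma, 97 were called, 63 higher and 34 lower in oxidized cells, and 2371 had an unadjusted p under 0.05. Median-ratio scaling gave 57 higher and 51 lower, and quantile normalization 54 and 51. With the population as a block, 2 higher and 2 lower genes were called: Frzb (adjusted p = 0.0422), Eno1b (0.00944), Gm21982 (0.00178) and Gm15454 (0.00614). The last pair fell outside the naming rule and was chosen after the values were seen. Of these calls only Frzb shares no sequence, as 84.5%, 90.5% and 87.8% of the stretches of Eno1b, Gm21982 and Gm15454 occur in other genes. Fragments moved between copies stay open for Gm21982 and Gm15454. The other 93 of the 97 had blocked adjusted p-values from 0.0540 to 0.105. Among them were H2ac13, Crabp1, T and every other gene listed above under the largest increases and decreases. Without 1 library the counts were 3 (oxidized A), 4 (oxidized B), 1185 (oxidized C), 4 (reduced A), 3 (reduced B) and 64 (reduced C), and without the oxidized libraries A and B together 4 genes were called, 2 of them among the 97, Eno1b included. Without genes that share sequence, 206 of 10354 genes were called.

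Of the germ layer and cell type lists, the primitive and visceral endoderm list was the most clearly raised in oxidized cells. These are genes of the extraembryonic endoderm and its basement membrane, and 15 of 16 measured members had positive differences, with a median of 0.86 on the log2 scale (adjusted p = 7.1e-08; adjusted p = 0.235 with an estimated correlation). Col4a2, a chain of type IV collagen, rose from 5.12 ± 0.371 to 14.3 ± 2.71 FPKM, and the matrix glycoprotein gene Sparc from 56.1 ± 10.3 to 132 ± 25.1 FPKM. Col4a2 overlaps Col4a1, at 14.2 against 7.26 FPKM, so its value is uncertain. Those were the 2 members called over all genes, while 12 passed when adjusted over the list alone, among them the transthyretin gene Ttr, at 2.22 ± 0.907 against 0.351 ± 0.107 FPKM (adjusted p = 0.0599 over all genes). Col4a2 and Sparc had blocked adjusted p-values of 0.0665 and 0.0902. In oxidized C alone, the mean log2(FPKM + 1) of this list was 3.13, against 2.33 to 2.46 in the reduced libraries.

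Fibroblast and mesenchyme genes were also raised, with positive differences in 10 of 11 members and a median of 0.81 (adjusted p = 0.00222; adjusted p = 0.755 with an estimated correlation). Of these 2 were called over all genes and 7 when adjusted over the list alone. Fbln1, a matrix protein, rose from 11.9 ± 1.99 to 33.8 ± 8.32 FPKM, with a blocked adjusted p of 0.0875, and Col3a1 was the other called member. The gelatinase gene Mmp2 was at 71.3 ± 12.6 against 39.4 ± 4.86 FPKM (adjusted p = 0.0780). Cardiac progenitor and cardiomyocyte genes had a median of 0.57 over 11 members, with 0 called and 6 adjusted over the list alone (adjusted p = 0.00783; adjusted p = 0.755 with an estimated correlation). Its leading members were the sarcomere genes Tnni1 (1.13, adjusted p = 0.0654), Myl3 (0.81, 0.0737) and Actc1 (0.80, 0.0921), where Myl3 is uncertain, as it overlaps Pth1r, at 12.2 against 4.12 FPKM. Of the 21 genes of the neuroectoderm list only 7 passed the filter. They had a median of 0.57, with 0 called and 4 adjusted over the list alone (adjusted p = 0.00783, and 0.755 with an estimated correlation). At a mean of at least 5 FPKM this list had too few members for a test. Its leading members were the transcription factor gene Irx3, at 10.98 ± 4.34 against 2.27 ± 1.54 FPKM (adjusted p = 0.0599), the cadherin gene Cdh2 (log2 difference 0.88) and the intermediate filament gene Nes (0.81). Without oxidized C the fibroblast and cardiac lists lost their call (adjusted p = 0.202 and 0.183), and without oxidized A and B the neuroectoderm list did (0.146).

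Imprinted genes had a median of 0.52 over 15 members (adjusted p = 0.00938; adjusted p = 0.755 with an estimated correlation). Nnat, the growth factor gene Igf2 and the signalling adaptor gene Grb10 were the 3 called members, and 8 passed when adjusted over the list alone. Igf2 rose from 28.1 ± 11.9 to 83.6 ± 17.6 FPKM, uncertain as 75.9% of its stretches lie in an overlapping gene, and Grb10 from 4.001 ± 0.560 to 8.79 ± 0.575 FPKM, each with a blocked adjusted p of 0.0902. The log2 fold change of Igf2 also lost its call with median-ratio scaling (adjusted p = 0.0540), without the mean-variance trend (0.0514) and with a pseudocount of 0.1 (0.0546). Of the 20 genes of the Hox list only 7 passed the filter. All 7 had positive differences, with a median of 0.39, 0 called and 1 adjusted over the list alone (adjusted p = 0.0441, and 0.808 with an estimated correlation). Hoxb2 was at 2.40 ± 0.837 against 0.943 ± 0.155 FPKM, and Hoxd9 at 7.02 ± 2.06 against 3.68 ± 1.47 FPKM, and the log2 difference of Hoxd1 was 0.41. The imprinted list lost its call without oxidized C (adjusted p = 0.307). The Hox list lost its call without oxidized A (0.138), oxidized C (0.0856), reduced A (0.0972), reduced B (0.125) or oxidized A and B together (0.147).

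Of 13 measured primordial germ cell genes 10 had negative differences in oxidized cells, with a median of -0.50 (adjusted p = 4.0e-04; adjusted p = 0.755 with an estimated correlation). The RNA helicase gene Ddx4 fell from 4.40 ± 0.719 to 1.58 ± 0.402 FPKM and was the 1 member called. The log2 fold change of Ddx4 had an adjusted p of 0.0782 in the blocked fit and 0.0501 with a pseudocount of 0.1, while 4 members passed when adjusted over the list alone. Naive pluripotency genes had a median of -0.34 over 14 members (adjusted p = 0.00233; adjusted p = 0.755 with an estimated correlation), with 0 called and 3 adjusted over the list alone. The mean log2(FPKM + 1) of the naive list was 4.03 and 4.24 in oxidized A and B, within the reduced range of 4.01 to 4.37, and 3.44 in oxidized C. Tfcp2l1 and Dppa3, which both lists hold, were at 2.50 ± 0.742 against 6.09 ± 0.963 FPKM (adjusted p = 0.0666) and at 108 ± 16.3 against 166 ± 5.10 FPKM (0.114). Zfp42 (Rex1) was at 45.6 ± 9.23 against 95.7 ± 36.2 FPKM (0.138). Without oxidized C the naive list had an adjusted p of 0.202 and the germ cell list 0.0276.

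Primitive streak genes, which pattern the gastrulating embryo, had a median of -0.16 over 15 members (adjusted p = 0.0267; adjusted p = 0.755 with an estimated correlation). T was the 1 called member, and 1 higher and 3 lower passed when adjusted over the list alone. Fgf8 was at 32.4 ± 3.67 against 53.2 ± 6.45 FPKM (adjusted p = 0.0947), while Cer1, a secreted Nodal antagonist, had a positive difference of 0.77 (0.129). Genes of G2 and mitosis had a median of -0.09 over 22 members, with 0 called and 0 adjusted over the list alone (adjusted p = 0.0441; adjusted p = 0.808 with an estimated correlation). The mean log2(FPKM + 1) of this list was 5.42 and 5.39 in oxidized A and B, within the reduced range of 5.26 to 5.53, and 5.10 in oxidized C. Aurka, Top2a and Ccnb1 had differences of -0.46, -0.41 and -0.38. Without oxidized C the streak and mitotic lists had adjusted p-values of 0.211 and 0.405, without reduced A 0.0972 and 0.0752, and without reduced B the mitotic list had 0.217, as against 0.0700 without genes that share sequence.

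**Figure D3:**
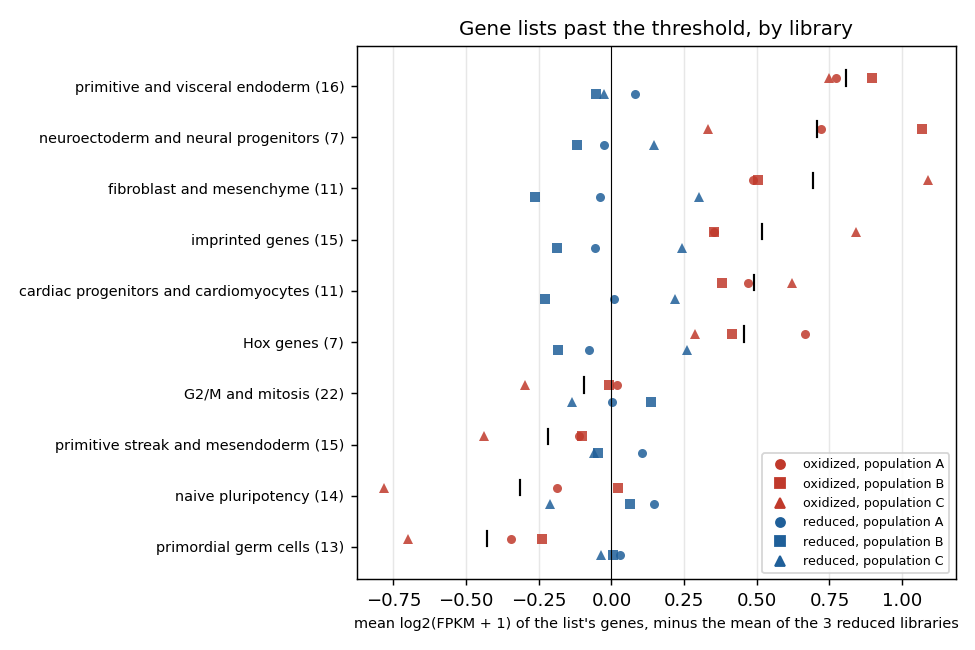
Mean log2(FPKM + 1) of the measured members of the 10 lists past the threshold, in each library, minus the mean of the 3 reduced libraries, with the member number in brackets and the vertical tick giving the mean of the oxidized libraries. The 3 oxidized libraries lie at 0.75 to 0.90 for the primitive and visceral endoderm list, and oxidized C lies lowest for the naive pluripotency, germ cell, streak and mitotic lists.

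Members of the two-cell-like state were too few for a list test, as 2 of 11 passed the filter. Zscan4f, a marker of the rare cells in stem cell cultures that resemble two-cell embryos (chr7:11397915-11402318), was listed at 0 in all 3 oxidized libraries and at 2.03, 2.97 and 1.64 FPKM in the reduced ones (adjusted p = 0.0158; 0.0595 with the block), uncertain as 95.3% of its stretches are shared. The translation factor gene Eif1a was at 54.6, 44.8 and 12.7 FPKM in oxidized A, B and C against 12.8 to 14.1 FPKM (adjusted p = 0.205). When adjusted over the list alone, 1 was higher and 1 lower.

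No list of redox or energy metabolism passed the test. The NRF2 and glutathione list had 0 of 22 members called, the peroxide and thiol enzymes 0 of 24, glycolysis 0 of 21, the hypoxia response 0 of 20, nuclear-encoded oxidative phosphorylation 0 of 33 and mitochondrially encoded transcripts 0 of 13, and 0 in each when adjusted over the list alone. Their adjusted p-values were 0.758, 0.614, 0.858, 0.932, 0.0636 and 0.0956, with medians of 0.07, 0.24, 0.11, 0.14, 0.22 and 0.83. The NRF2, glycolysis and hypoxia lists had positive medians and means while camera gave the lower direction. Gclm, a subunit of the enzyme that makes the glutathione precursor, was at 12.01 ± 3.17 against 13.1 ± 1.38 FPKM (adjusted p = 0.744), uncertain as it overlaps other genes in the table, and thioredoxin (Txn1) at 370 ± 92.7 against 279 ± 29.1 FPKM (0.345). Of the most abundant members, Prdx1 differed by -0.25, ferritin light chain (Ftl1) by -0.21, Ldha by 0.15, Slc2a1 by 0.44, Atp5b by 0.24 and mt-Co1 by 0.54, all with adjusted p-values of 0.286 or higher. Without 1 library the oxidative phosphorylation list was called higher (adjusted p = 0.0115 without oxidized B, 0.0449 without oxidized C, 0.00961 without reduced C), and so was the mitochondrially encoded list (0.00228 without oxidized C, 0.0188 without reduced B). The mean log2(FPKM + 1) of the mitochondrially encoded list was 8.30 and 7.96 in oxidized A and B. It was 6.99 in oxidized C and 6.62 to 7.24 in the reduced libraries. Without oxidized A and B, which leaves 1 oxidized library, the direction of this list was lower. The mean of the glycolysis list was 6.94 and 6.96 in oxidized A and B, above the reduced range of 6.57 to 6.93. In oxidized C it was 6.47, below that range, so the populations differ in direction.

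The remaining lists did not pass either. For core and primed pluripotency (median -0.05, adjusted p = 0.234) 1 of 17 members was called, Tdgf1, and 1 adjusted over the list alone. Pou5f1 was at 119 ± 40.7 against 183 ± 15.7 FPKM (adjusted p = 0.209), Sox2 at 47.4 ± 11.9 against 61.0 ± 9.13 FPKM (0.352), Nanog at 34.9 ± 20.4 against 23.2 ± 4.62 FPKM (0.707), and Utf1 differed by -0.28. Nanog was at 44.3 and 49.0 FPKM in oxidized A and B, above the reduced range of 18.2 to 27.2. In oxidized C it was at 11.5 FPKM, below that range. Utf1 was at 186, 261 and 62.9 FPKM in oxidized A, B and C, against 154 to 216. For mesoderm (median 0.44, adjusted p = 0.235) 0 of 14 were called, with 4 higher and 1 lower adjusted over the list alone, and Hand1 was at 156 ± 30.6 against 80.8 ± 17.4 FPKM (0.0877). For definitive endoderm (median 0.08, against the lower direction in camera, adjusted p = 0.992) Trh was the 1 of 10 called, with 2 higher and 1 lower adjusted over the list alone; Sox17 differed by 0.34 and Krt8 by -0.01. The core pluripotency list was called lower without oxidized B (adjusted p = 0.0115) and without oxidized A and B (8.3e-04), and the mesoderm list was called higher without oxidized A and B (0.0231). Pax6 lay below the filter, at 0.267 ± 0.184 against 0.182 ± 0.00677 FPKM.

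Haemato-endothelial genes (adjusted p = 0.746), trophoblast genes (0.614), neurons (0.397) and neural crest and surface ectoderm (0.0855) had 0 called of 14, 9, 7 and 7 members. Adjusted over the list alone, 1, 3, 0 and 2 were higher, and 1 trophoblast gene was lower. The embryonic globin gene Hbb-bh1 differed by 0.71, Ina, which overlaps Nt5c2 and is uncertain, by -0.60 and Msx1 by 0.62. The integrated stress response (adjusted p = 0.114), p53 targets (0.441), heat shock (0.932) and immediate early genes (0.758) had 0 called of 21, 20, 19 and 16 members. Adjusted over the list alone, 1 was higher and 2 lower in the stress response, 3 were higher among immediate early genes, and 0 in the others. For p53 targets the median was -0.03 and the mean 0.00. Gars, Bax, Hsp90ab1 and Ier2 differed by -0.19, -0.18, -0.33 and 0.40. Cytosolic ribosomal proteins (0.234), histones (0.314), cholesterol biosynthesis (0.433) and DNA replication genes (0.906) had 0 called of 32, 17, 19 and 21 members, and 0 adjusted over the list alone. Rpl8, H1f5, Mvd and Mcm5 differed by -0.63, -1.09, 0.16 and 0.28, with adjusted p-values of 0.233, 0.401, 0.636 and 0.421, and H1f5 went from -1.96 without oxidized C to -0.39 without oxidized B. Lists of this group called without 1 library were ribosomal proteins, lower without oxidized A (adjusted p = 0.0284), and neural crest, higher without oxidized B (0.0447) or reduced C (0.0194). Histones (0.0336) and the integrated stress response (0.0187) were called lower without reduced B, and haemato-endothelial genes higher without reduced C (0.0261). The mean log2(FPKM + 1) of the haemato-endothelial list was 2.46, 2.30 and 3.41 in oxidized A, B and C. In reduced A, B and C it was 1.99, 2.17 and 3.42.

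In the authors' deposited table, 864 genes had a q-value under 0.05, 475 higher and 389 lower in oxidized cells, and 605 of the table's genes were marked significant. Of the 97 genes called with limma 92 had a q-value under 0.05 in the authors' deposited table. All 97 had the same direction there, which is no independent support, as the deposited ratio comes from the same FPKM values. Of the 864 genes 192 lay below the filter on low values used here.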

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

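The alternatives without the oxidized libraries A and B, which leaves 1 oxidized library assumed to vary like the others, and without genes that share sequence were chosen after seeing the data. With the population as a block, limma called 2 genes higher and 2 lower in oxidized cells, with 2345 at an unadjusted p under 0.05 against 2371 without it; the block leaves 2 residual degrees of freedom in place of 4, and it changed no list call. Without a filter on low values 28179 genes were tested, and 1 was called higher and 0 lower. A mean of at least 5 FPKM gave 21 lower, with fewer genes tested. Leaving out 1 library gave between 1 and 884 higher and between 2 and 301 lower, where the highest counts came without oxidized C. Without the oxidized libraries A and B 3 were higher and 1 lower, and without genes that share sequence 139 and 67. The other settings stayed within 1.5 times of the main counts.

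For the lists, camera with an estimated correlation called 0 higher and 0 lower, and no filter gave 10 higher. Leaving out 1 library gave between 4 and 9 higher lists and between 1 and 5 lower ones, with 1 without oxidized C and 2 without reduced A. With the estimated correlation the primitive and visceral endoderm and germ cell lists lost their call (adjusted p = 0.235 and 0.755). In the 14 remaining settings, including that with 1 oxidized library, both kept it, with adjusted p-values up to 0.00380 and 0.0276. The mitochondrially encoded list was called higher with median-ratio scaling (0.0375), quantile normalization (0.0202), no filter (0.0482) and without genes that share sequence (0.0380), and the oxidative phosphorylation list with quantile normalization (0.0318) and no filter (0.00865). With no filter the mesoderm (0.00221) and neural crest (0.0132) lists were called higher too, and at a mean of at least 5 FPKM the integrated stress response was called lower (0.0431). Without a filter the two-cell-like list had enough members for the test and was lower (adjusted p = 1.1e-04).

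Of the 23 named genes that were called, none kept its call without a filter. Median-ratio scaling ended the call of Igf2, dropping the trend those of Spink1 and Igf2, and a pseudocount of 0.1 those of Ddx4 and Igf2. Among named genes the reversals were in genes not called. Without oxidized A and B, Krt8 differed by 0.53, Eif1a by -0.068, Ldha by -0.083, Atp5b by -0.20, mt-Co1 by -0.055, H1f5 by 0.67, Nanog by -0.93 and Sox17 by -0.20. Leaving out 1 library gave a range of -0.70 to 0.31 for Utf1, -0.13 to 1.93 for Hbb-bh1, -0.28 to 0.22 for Krt8, -0.0046 to 0.99 for Nanog and -0.29 to 0.068 for Gclm. It moved none of the 23 named genes that were called by over 1.5 times, but besides these 5 it did so for 18 that were not: Eif1a (0.80 to 1.82), mt-Co1 (0.28 to 0.83), Ldha (0.036 to 0.26), Atp5b (0.096 to 0.46), H1f5 (-1.96 to -0.39), Sox17 (0.058 to 0.61), Pou5f1 (-0.88 to -0.36), Sox2 (-0.57 to -0.26), Txn1 (0.19 to 0.54), Ftl1 (-0.42 to -0.034), Prdx1 (-0.40 to -0.11), Bax (-0.32 to -0.081), Mcm5 (0.16 to 0.42), Mvd (0.052 to 0.25), Top2a (-0.57 to -0.24), Ccnb1 (-0.50 to -0.21), Ier2 (0.27 to 0.52) and Msx1 (0.37 to 0.85). Scaling by median ratios moved the median difference of all genes from 0.08 to -0.01. The causes were not tested. Leaving out loci with no gene symbol was planned but not run, as every gene in the table has one.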

Other observations

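The gene ontology test, the sequence searches, and the tests on other splits for the gene count, on population C, on Eno1b, on the endoderm and streak scores and on Zscan4 were chosen only after the results they bear on were seen.

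Genes that act outside the cell made up much of the increase in oxidized cells. Of 56 genes called higher that carry an ontology term, 21 belong to the extracellular region, against 2.47 expected (one-sided hypergeometric test, adjusted p = 2.0e-11), and 15 of 2736 terms passed. The basement membrane held 7 against 0.290 expected (adjusted p = 7.5e-06): Col4a2, Sparc, Fbln1, the lysyl oxidase gene Loxl2, the growth factor gene Ptn, Serpinf1 and Tgfbi. The collagen-containing matrix held 10 against 0.664 expected (adjusted p = 7.9e-07), among them Col3a1, Emilin1 and Mfap4. For the 27 genes called lower that carry a term, 0 terms passed. These terms rest on 63 higher calls made without the block, of which 2 remained with it. The hypergeometric test also takes genes as independent, so its p-values are too small where genes vary together. Col4a2, Sparc, Fbln1 and Col3a1 are the called members of the endoderm and fibroblast lists too. Those lists lost their call in camera with an estimated correlation (adjusted p = 0.235 and 0.755).

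The Zscan4 cluster of chromosome 7 was almost silent in oxidized cells. Its 9 annotated genes and pseudogenes, among them Zscan4c, Zscan4d and Zscan4f, were each lower in all 3 oxidized than in all 3 reduced libraries. Their FPKM summed to 0.962, 0.144 and 0 in oxidized A, B and C and to 8.41, 11.2 and 6.63 in reduced A, B and C (exact permutation p = 0.1, the smallest that 3 against 3 can give, two-sided). Usp17la and Gm12794 of the two-cell-like list were listed at 0 in all oxidized and above 0 in all reduced libraries, while Eif1a and the other members overlapped. Lower depth is argued against, since at the level of the lowest reduced library each oxidized library would hold at least 164 fragments where 32.6, 5.00 and 0 were estimated. That bound, 3 fragments, replaced a first bound of a 10-fold shortfall in each oxidized library, which oxidized A missed at 8.99. Fragments moved between the annotated copies are argued against too, since the sums leave a gap of 5.67 FPKM between the groups (pooled SD 1.68). Both tests were set after these values were seen, and whether the share of cells or the level in each cell differed stays open and was not tested.

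The first pattern to weigh is the 97 called genes and 10 called lists. The 6 libraries make 10 splits, too few for a share under 0.05. For genes, 1 split reached 97, the real one, and the highest other gave 3. For lists, 4 splits reached 10, the real one included, so the number of called lists does not set the real grouping apart. The highest other split gave 16, with oxidized A, oxidized C and reduced C against the rest. Among the 3 other splits that part all 3 population pairs the highest were 3 genes and 6 lists. Length or GC content bias is argued against as the whole cause of these gene calls, since 92 of 97 stayed past the threshold once each library's trend was taken out, with the median size of change going from 1.34 to 1.26. The correction did change the count, to 208 genes, 97 higher and 111 lower, so the balance of 63 higher to 34 lower does not hold under it. The composition of oxidized A and B stays open, as 67.9% of 755 genes chosen in populations A and B had the same direction in C, with a median of 0.19 there against 1.22. Without genes that share sequence it was 73.6% of 564. Of genes chosen with population A or B held out, 84.2% of 38 and 81.25% of 32 kept their direction in the held-out population. The redox state itself, which the design names, stays open as well and was not tested.

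Eno1b is the second pattern. FPKM times transcript length in kilobases, a measure of fragments, fell from 3066 to 447, while its 4 annotated near-identical copies, Eno1 among them, summed to 2519 ± 94.7 in oxidized and 2791 ± 87.9 in reduced libraries (n = 3 each). The copies' gain was thus -10.4% of the loss, which argues against fragments that moved to annotated copies. Fragments from a copy outside the annotation, and how fragments with several matches were placed, stay open and were not tested. For the other 13 called genes with copies, 8 had an offset of less than 50% of their change and 5 could not be resolved beyond the spread, so moved fragments stay open for those.

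A hypothesis for the lists was that the oxidized cells may hold fewer pluripotent cells, with all other cell types in proportion. The endoderm score minus the primitive streak score was 0.32 ± 0.15 in oxidized and -0.70 ± 0.03 in reduced libraries (n = 3 each), a difference of 1.02 with a pooled SD of 0.11. A uniform shift of all other cell types would leave this difference near 0. Both lists had already been called, in opposite directions, so the difference follows from those calls and is no separate test. The mean log2(FPKM + 1) of the naive pluripotency list was 4.03 and 4.24 in oxidized A and B, within the reduced range of 4.01 to 4.37. It was 3.44 in oxidized C, below that range. The germ cell list was at 3.17, 3.27 and 2.81 in oxidized A, B and C, all below the reduced range of 3.47 to 3.54. These values are mixed, and whether pluripotent cells also express the streak genes was not tested, so the hypothesis stays open. A change of the endoderm itself, or of expression within cell types, stays open as well.

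Gm21982, the largest increase of all called genes, was at 15.7 ± 2.41 against 0.263 ± 0.0716 FPKM, with 90.5% of its stretches shared with other genes, Rbm42 and Haus5 among them.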
